A study of Arabidopsis thaliana with 18 samples.

How the data were processed

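The series holds 18 Affymetrix arrays of RNA from Arabidopsis thaliana Col-0 rosette leaves, 3 for each of 6 groups. Per the labels' protocols, plants 19 to 21 days old, grown in soil at 21 °C with 11 h of light and 13 h of dark, were placed in groups of 3 in airtight glass vessels of 22 L. A volume of 50 µl of E-2-hexenal in methanol, or of methanol alone, was put on a cotton swab among them. RNA was extracted with TRIzol and cleaned on columns, and biotin-labelled cRNA was hybridised, per the labels' protocols.

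The values used were those of the authors' deposited table, 1 log2 value per probe set and array. The deposited log2 scale was taken from the range of the values, 2.24 to 14, since a natural log of such values would pass the range of a scanner and a log10 scale could not hold them. The software, background correction and normalization between arrays behind these values are not given in the sources used here. The table had 22746 probe sets, no missing value and 0 control probe sets. No signal over background is part of the table, so depth is represented only by the 3 arrays per group. No column of another series was present.

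Gene names came from the platform annotation, with symbols updated by gene number through a RefSeq gene table of assembly TAIR10.1. Of the probe sets, 13513 were given 1 gene, 503 several and 8730 none, and 13436 of the first were found in the gene table. No gene was named from a probe set with several genes. For 144 genes with more than 1 probe set the one with the highest mean over all arrays stood for the gene, and no such gene had probe sets called in opposite directions in a comparison of hexenal with mock. No genome build is named for the array, so no coordinates are given.

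Each comparison was made with limma 3.58.1 in R 4.3.3 on the log2 values, with a mean per group over all 18 arrays, moderated variances and Benjamini-Hochberg adjustment over the 22746 probe sets of each contrast. A probe set was called at an adjusted p under 0.05. The contrasts were hexenal against mock at each time, the 3 treatment by time interactions, and mock at 3 h and 24 h against mock at 1 h. Changes are differences of group means with limma's standard error unless a SD is named. That error rests on 1 moderated variance per probe set over all 6 groups. It is thus the same for hexenal against mock at each time and is not the spread of the arrays compared. The steps were tested on simulated data with 200 changed probe sets, made from each probe set's mock mean and residual SD with independent normal noise. At a log2 change of 2, 89.6% were recovered at 1 h, 88.1% at 3 h and 88.1% at 24 h, and at a log2 change of 1, 62.7% at 24 h. For the interactions at a log2 change of 1 it was 38.8% to 43.3%. The simulation had equal spread in all groups and no shared replicate effects, so these rates check the steps and do not give the power of this experiment.

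Before the data were examined, 27 gene lists with 511 entries, the contrasts, the rule for named genes and the alternatives were fixed. A list gene was matched by locus, 1 was left out because its symbol belongs to another locus, and 102 had a named probe set. Lists with 3 or more measured genes, 16 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, which tests whether a list's genes move one way or, as its mixed test, in either direction; that minimum was chosen after the annotation was seen. The named genes per hexenal contrast were the 10 largest rises and 10 largest falls among probe sets of a single gene that passed the threshold, had a mean at or above the median probe set mean of 5.44, and had no overlap between the 3 hexenal and 3 mock arrays. To these were added up to 3 called members per list with the largest change, and 5 rises and 5 falls per other contrast without the condition on overlap. WRKY6, WRKY53, WRKY40, POP2 and GAD4 were to be named in any case. The annotation used gave the last 3 of these no probe set of their own, so no value is reported for them. It left 8730 probe sets without a gene, so this does not show that the array cannot measure them. Members of lists that did not pass could be named with their values. The called list members PUB22, CML42 and ALDH3F1, the interaction of STZ and the proteasome genes stand outside this rule and were chosen after their values were seen, as were PDF1.2b and AT5G02540 at 24 h.

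No 2 arrays held identical values. Same-numbered hexenal and mock arrays were checked for pairing through the correlation of their deviations from the group means across probe sets. It was 0.727, 0.802 and 0.428 at 24 h, where all 3 pairs passed 0.1, and it fell below 0.1 for some pairs at 1 h and 3 h. Deviations shared by all pairs were thus seen at 24 h only. Low values do not show that arrays were unpaired, since the hexenal arrays at 1 h and 3 h also differed in response size. The labels speak of 3 independent experiments. With the replicate number as a block over all times no probe set passed at 24 h, and in the fit of that time alone with the block 1 did.

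The alternatives were the replicate block, the brighter probe sets alone, quantile normalization, median centring, array weights, an intensity trend with a robust prior, fits of the compared arrays alone, stricter thresholds, and leaving out each array or each replicate number. The default estimation of array weights did not converge, so weights were estimated gene by gene, a method chosen after that failure. These weights differed widely between arrays of a group and may be overstated, so counts with them are to be read with caution. Pseudocounts did not apply to log2 values. Alternatives added after the data were seen were a replicate block within each time, that block in fits of 1 time alone, variance weights per group, and 31 gene families formed from gene symbols.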

Results

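Gene expression was measured in rosette leaves of Arabidopsis thaliana Col-0, the standard laboratory accession, after exposure to vapour of E-2-hexenal, a reactive 6-carbon aldehyde that leaves release on wounding. Plants in closed glass vessels received the aldehyde at 3 µM in the air or methanol, its carrier, as mock, and leaves were taken after 1, 3 and 24 h. Each of the 6 groups held 3 arrays, 1 from each of 3 independent experiments, so that 18 arrays with 22746 probe sets were compared. The deposited log2 values ran from 2.24 to 14, and the array medians lay between 5.19 and 5.46. Within groups the correlation between arrays across probe sets lay between 0.989 and 0.996 in mock at 1 h, between 0.993 and 0.997 in mock at 3 h, and between 0.958 and 0.987 in mock at 24 h. In hexenal it lay between 0.975 and 0.991 at 1 h, between 0.902 and 0.977 at 3 h, and between 0.962 and 0.989 at 24 h. The number of arrays, 3 per group, limits the precision of each value below.

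At 1 h, hexenal raised genes of xenobiotic and carbonyl detoxification, of touch, calcium and ZAT signalling and of immunity, lists with limma camera adjusted p between 6.08e-09 and 1.74e-05. UGT73B5 (AT2G15480), a glycosyltransferase, was higher by 6.84 ± 0.44 on the log2 scale (SE, n = 3 arrays per group), and the small heat shock protein gene AT2G29500 by 6.98 ± 0.74. The mock means of these genes, 3.89 and 3.71, lay near the first quartiles of the arrays (3.54 to 3.70). Those of AT1G05575, CML37, CML38, UGT73B4, UGT73C1, AT5G16980 and GRX480, given below, lay between 3.14 and 3.79. Among genes that fell, also given below, the hexenal means of AT4G09890, IAA29 and AT5G59350 were 3.83, 3.89 and 4.09. Signal over background is not part of the table, so whether these mock and hexenal values stood above it is not known. AER (AT5G16970), an alkenal reductase that acts on unsaturated aldehydes, rose by 4.02 ± 0.25, from 6.73 ± 0.14 to 10.75 ± 0.35 (SD, n = 3). The expansin gene EXPA8 (AT2G40610), whose product loosens cell walls, fell by 4.12 ± 0.99 on the log2 scale, a call lost without any of 5 of the 6 arrays. With limma and Benjamini-Hochberg adjustment, 1191 of 22746 probe sets passed an adjusted p of 0.05, 882 higher and 309 lower, and 930 of them changed at least 2-fold.

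The other large rises at 1 h were those of AT1G05575 (6.89 ± 1.23), AT4G01870 (6.46 ± 0.33), the small heat shock protein gene AT5G51440 (6.19 ± 0.91), AT1G76600 (6.17 ± 0.67), AT1G66090 (5.95 ± 0.89), AT5G25930 (5.88 ± 0.82), the zinc finger gene STZ (AT1G27730, 5.87 ± 0.70) and AT4G13180 (5.63 ± 0.39). Their limma Benjamini-Hochberg adjusted p ranged from 4.49e-08 for AT4G01870 to 0.00402 for AT1G05575. Large falls were those of AT5G62280 (-3.54 ± 0.96), the homeodomain gene HAT2 (AT5G47370, -3.49 ± 0.78), AT4G09890 (-2.91 ± 0.63), AT5G66590 (6.05-fold lower, SE 0.47 on the log2 scale), AT5G59350 (-2.39 ± 0.60), AT3G50340 (-2.35 ± 0.42), AOP1 (AT4G03070, -2.11 ± 0.42), AT1G18810 (-2.10 ± 0.51) and AT2G47440 (-2.06 ± 0.52). In each of these genes the 3 hexenal arrays lay all above or all below the 3 mock arrays. The rule for naming them required this, so it adds no support. The calls of 23 of the 38 genes named for 1 h held when each of the 6 arrays was left out in turn. Calls were lost without 5 of the arrays for EXPA8, HAT2, AT5G62280, AT5G59350, AT1G18810, AT2G47440, CML37 and BZIP28, and without 4 for AT4G09890 and Hop3. They were lost without 3 arrays for PUB23 and BZIP60, without 2 for UGT73B4, and without 1 for AOP1 and GRX480. The count itself was 2010 without hexenal replicate 2, 468 and 509 without hexenal replicates 1 and 3. It was 627, 718 and 681 without mock replicates 1, 2 and 3, and 1833 in a fit of the 1 h arrays alone, 1014 higher and 819 lower. Variance weights per group gave 1593 higher and 1492 lower, and with array weights falls were the more numerous, 2251 higher and 3483 lower.

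Of 16 gene lists with 3 or more measured members, 6 passed the camera test at 1 h (limma, Benjamini-Hochberg adjusted), all upward. The measured genes were only a part of each of these lists. They were 6 of 15 in touch, calcium and ZAT signalling, 4 of 26 in immunity and 5 of 24 in xenobiotic detoxification. In carbonyl detoxification they were 8 of 18, among WRKY factors 5 of 32 and in heat shock 7 of 31. Among 6 measured genes of touch, calcium and ZAT signalling, 4 rose: STZ, the calmodulin-like genes CML38 (4.72 ± 0.56) and CML37 (3.55 ± 0.94), and CML42 (camera adjusted p = 6.08e-09; 5 adjusted over the list alone). All 4 measured genes of pattern-triggered immunity rose, the U-box ubiquitin ligases PUB24 (3.93 ± 0.40), PUB23 (3.60 ± 0.75) and PUB22 (6.05-fold, SE 0.57 on the log2 scale, a call lost without 3 of the 6 arrays) and the receptor-like cytoplasmic kinase gene BIK1 (3.13 ± 0.49; camera adjusted p = 6.08e-09; 4 adjusted over the list alone). Of 5 xenobiotic detoxification genes, UGT73B5, UGT73B4 (3.43 ± 0.70) and UGT73C1 (3.34 ± 0.41) rose (camera adjusted p = 2.87e-08; 4 adjusted over the list alone). Of 8 carbonyl detoxification genes, AER and its relatives AT5G16980 (4.68 ± 0.59) and AT5G16960 (2.43 ± 0.36) rose (camera adjusted p = 1.74e-05), and adjusted over the list alone 4 rose and 1, ALDH3F1, fell. Of 5 WRKY transcription factor genes, WRKY6 (4.56 ± 0.58) and WRKY53 (4.48 ± 0.37) rose (camera adjusted p = 0.00057), and adjusted over the list alone 3 rose and 1 fell. These 5 lists held with an estimated correlation, with adjusted p between 0.0211 and 0.0272.

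Of 7 heat shock genes at 1 h, AT2G29500, the immunophilin gene ROF2 (AT5G48570, 5.01 ± 0.88) and the co-chaperone gene Hop3 (AT4G12400, 4.92 ± 1.07) rose (camera adjusted p = 1.48e-07; 4 adjusted over the list alone), and this list gave adjusted p = 0.0998 with an estimated correlation. The other 10 lists tested did not pass camera at 1 h. By fry, which does not compare a list with other genes, the same 6 passed, and the auxin and expansin list passed downward (adjusted p = 0.0261, against 0.283 by camera). Among their members, the unfolded protein response factors BZIP60 (1.98 ± 0.43) and BZIP28 (1.47 ± 0.40) rose, as 2 of 4 measured (2 rises and 1 fall adjusted over the list alone). In the auxin and expansin list EXPA8 and IAA29 (-1.92 ± 0.33) fell, as 2 of 5 (2 adjusted over the list alone). None of 8 glutathione transferase, 10 photosynthesis, 5 jasmonate response, 4 phenylpropanoid, 4 abscisic acid, 4 starvation, 3 hypoxia or 6 reference genes passed limma at 1 h, and adjusted over the list alone 2 glutathione transferase genes did. Of the lists with 1 or 2 measured members, the salicylate response gene GRX480 rose (4.46 ± 0.86), with 2 of 2 adjusted over the list alone. No gene of jasmonate biosynthesis, tryptophan or aliphatic glucosinolate metabolism, the ERF factors or the clock passed, and adjusted over the list alone 1 of 2 jasmonate biosynthesis and 1 of 2 tryptophan genes did. Measured were 2 of 16 jasmonate biosynthesis, 2 of 18 tryptophan, 2 of 15 aliphatic glucosinolate, 1 of 22 ERF and 1 of 18 clock genes. The single measured markers of guard cells (FMA, AT3G24140, -0.59 ± 0.26), phloem (SWEET11, -0.39 ± 0.38), roots (EXPA7, -0.19 ± 0.12) and trichomes (TRY, -0.95 ± 0.71) did not pass at 1 h either, nor at 3 or 24 h. As lists of 1 gene, so adjusted over the list alone, FMA was lower at 1 h and at 3 h (-0.73 ± 0.26), and EXPA7 at 24 h (-0.30 ± 0.12). No member of the GABA list had a probe set named for it alone in the annotation used, so that list was not examined.

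At 3 h, all 7 measured genes of the heat shock list rose by limma. AT2G29500 was higher by 8.31 ± 0.74 on the log2 scale (SE, n = 3 arrays per group), ROF2 by 6.19 ± 0.88 and Hop3 by 6.07 ± 1.07. The small heat shock protein gene AT5G51440, which is not in that list, was higher by 7.62 ± 0.91. AER remained higher, by 3.97 ± 0.25, and UGT73B5 by 6.33 ± 0.44. EXPA8 was lower by a log2 change of -4.64 ± 0.99, and DRT100 (AT3G12610) by -3.62 ± 0.80. Over the hexenal arrays at 3 h the SDs of these genes were 2.22 and 2.44, while the SE is pooled over all groups. With limma and Benjamini-Hochberg adjustment 4370 probe sets passed, 1973 higher and 2397 lower, and after median centring 2205 and 1932. Of the 4370, 2290 changed at least 2-fold, 1226 higher and 1064 lower. The fit of the 3 h arrays alone called 1067 probe sets, 572 higher and 495 lower, and that fit with the replicate number as a block, chosen after the data were seen, called 116, 100 higher and 16 lower.

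Further rises at 3 h were those of the small heat shock protein gene AT1G53540 (6.97 ± 1.79), AT4G01870 (6.77 ± 0.33), AT4G13180 (6.11 ± 0.39), AT5G61820 (5.62 ± 0.53) and SUFE2 (AT1G67810, 5.59 ± 0.50). AT1G53540 varied most, with a SD of 4.31 over the 3 hexenal arrays. Large falls were those of AT5G12050 (-3.93 ± 1.11), AT1G13650 (-3.81 ± 0.50), AT5G48900 (-3.80 ± 0.39), AT4G18970 (-3.59 ± 0.39), AT5G62280 (-3.57 ± 0.96), AT3G20820 (-3.53 ± 0.86), AT5G45670 (-3.53 ± 0.46) and the transcription factor gene BZIP61 (AT3G58120, -3.36 ± 0.90). The limma Benjamini-Hochberg adjusted p of the genes named by size at 3 h ranged from 3.18e-08 for AT4G01870 to 0.0255 for AT5G12050. The calls of 28 of the 42 genes named for 3 h held when each of the 6 arrays was left out in turn. Calls were lost without 5 of the arrays for AT5G62280, BIK1, CML38, BZIP28 and GRX480, and without 2 for WRKY6 and IGPS. They were lost without 4 arrays for AT1G53540, AT5G12050, BZIP61, PRK, ATPC1, LDH1 and UGT74C1. Mock means at 3 h were 2.94 for GSTU25 and 3.87 for AT5G51440, and those of AT2G29500, AT1G53540, UGT73B5, UGT73B4, UGT73C1, AT5G16980, GSTU22, CML38 and GRX480 lay between these values. The hexenal means of AT5G45670 and IAA29 were 3.38 and 3.64, and GSTU26, which was lower in hexenal, had a mock mean of 3.97. Whether these values stood above background is not known. The count was 7104 without hexenal replicate 2, 1887 without hexenal replicate 3, and 2172, 2386 and 2089 without mock replicates 1, 2 and 3.

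At 3 h, 8 of the 16 lists passed camera (limma, Benjamini-Hochberg adjusted), and none of the 8 held with an estimated correlation. By fry 7 of them passed, and the touch, calcium and ZAT list did not (adjusted p = 0.0797). All 7 heat shock genes rose, with a median log2 change of 6.07 (camera adjusted p = 8.1e-07, 0.197 with an estimated correlation; 7 adjusted over the list alone). UGT73B5, UGT73C1 (5.45 ± 0.41) and UGT73B4 (4.46 ± 0.70) rose among 5 xenobiotic detoxification genes (camera adjusted p = 1.4e-05, 0.190 with an estimated correlation; 4 adjusted over the list alone). Of 8 carbonyl detoxification genes 5 rose, with AT5G16980 at 5.18 ± 0.59 and the aldehyde dehydrogenase gene ALDH7B4 at 2.39 ± 0.29, and ALDH3F1 fell (-1.50 ± 0.42, lost without 4 of the 6 arrays; camera adjusted p = 0.000632, 0.106 with an estimated correlation; 5 rises and 1 fall adjusted over the list alone). Of 4 abscisic acid and dehydration genes, the dehydrin genes LTI30 (3.29 ± 0.40) and COR47 (0.89 ± 0.20) rose (camera adjusted p = 0.0251, 0.197 with an estimated correlation; 2 adjusted over the list alone). The immunity list passed (adjusted p = 0.0183, 0.388 with an estimated correlation) with 1 call, BIK1 (1.68 ± 0.49), lost without 5 of the 6 arrays, and 4 adjusted over the list alone. The touch, calcium and ZAT list passed (adjusted p = 0.0251, 0.409 with an estimated correlation) with 1 call, CML38 (1.78 ± 0.56), lost without 5 of the 6 arrays, and 2 adjusted over the list alone. After median centring, which moved the median of all probe sets by 0.10, the abscisic acid list and the touch list each had an adjusted p of 0.0517. The abscisic acid list had 0.0561 without hexenal replicate 2 and 0.0523 without mock replicate 3, and over its alternatives the adjusted p ran from 0.00863 to 0.0809. For the touch list it ran from 0.00986 to 0.0947, the highest without hexenal replicate 3. For the immunity list it ran from 0.00511 to 0.0794. That list did not pass with the brighter probe sets alone or without replicate 3 at every time.

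Lower at 3 h were the lists of photosynthesis and of auxin and expansin genes. All 10 measured photosynthesis genes, from a list of 38, had negative values. They did so at 1 h as well (median -0.14), where the list did not pass. At 3 h its camera adjusted p was 0.0106, and 0.409 with an estimated correlation. By limma 2 of the genes passed (also 2 adjusted over the list alone), those of phosphoribulokinase, PRK (-0.88 ± 0.29), and of the chloroplast ATP synthase gamma subunit, ATPC1 (-0.51 ± 0.16). Both calls were lost without 4 of the 6 arrays. Of 5 measured auxin and expansin genes, from a list of 15, EXPA8 and IAA29 (-2.66 ± 0.33) fell, also 2 adjusted over the list alone. The camera adjusted p of this list was 0.0264, and 0.197 with an estimated correlation. Without hexenal replicate 3 the photosynthesis list had an adjusted p of 0.0947, and without hexenal replicate 2 the auxin and expansin list had 0.0561. Over their alternatives the adjusted p ran from 0.0029 to 0.0996 and from 0.0123 to 0.360. The glutathione transferase list did not pass camera (adjusted p = 0.885) but changed in either direction by fry (adjusted p = 0.00454), with 3 of 8 genes higher, GSTU25 (5.58 ± 1.08), GSTU16 (1.95 ± 0.39) and GSTU22 (1.29 ± 0.35), and 2 lower, GSTU18 (-1.34 ± 0.24) and GSTU26 (-0.48 ± 0.15; 3 rises and 4 falls adjusted over the list alone). The call of GSTU22 was lost without 5 of the 6 arrays and that of GSTU26 without 4. Among WRKY factors WRKY6 rose (2.27 ± 0.58), a call lost without 2 of the 6 arrays, and WRKY53 had -0.09 ± 0.37. Single genes of other lists rose, BZIP28 (1.24 ± 0.40), GRX480 (3.02 ± 0.86) and IGPS of tryptophan synthesis (0.95 ± 0.24). So did IVD of the starvation list (1.33 ± 0.25) and LDH1 of the hypoxia list (1.70 ± 0.45), while UGT74C1 of aliphatic glucosinolate synthesis fell (-1.34 ± 0.37). Without 5 of the 6 arrays the calls of BZIP28 and GRX480 were lost, without 4 those of LDH1 and UGT74C1, and without 2 that of IGPS. Adjusted over the list alone 2 genes passed in the unfolded protein response and hypoxia lists and 1 in each of the other 5. No gene of the jasmonate, phenylpropanoid, ERF, clock or reference lists passed at 3 h. Most members of these lists were not measured. Values existed for 2 of 16 jasmonate biosynthesis, 5 of 26 jasmonate response, 4 of 24 phenylpropanoid, 1 of 22 ERF, 1 of 18 clock and 6 of 12 reference genes.

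**Figure D1:**
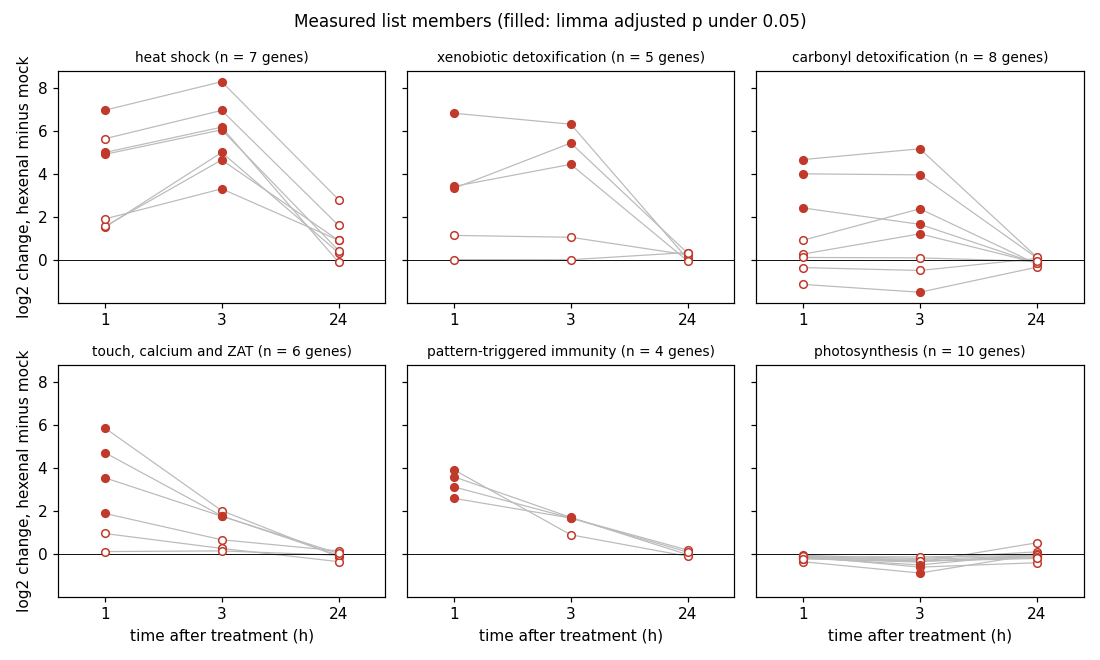
Log2 change, hexenal minus mock, of each measured member of 6 gene lists (vertical axis) at 1, 3 and 24 h (horizontal axis), with a line per gene and filled points for limma adjusted p under 0.05. All 7 heat shock genes are filled at 3 h, all 4 immunity genes at 1 h, and none of the points at 24 h.

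At 24 h, no probe set differed between hexenal and mock at the threshold. UGT73B5 (0.05 ± 0.44), AER (0.11 ± 0.25), WRKY6 (-0.04 ± 0.58) and WRKY53 (-0.49 ± 0.37) did not pass (log2 change ± SE, n = 3 arrays per group). The SE is pooled over all groups, and the SDs of UGT73B5 at 24 h were 0.04 in hexenal and 0.06 in mock. AT2G29500 was at 6.95 ± 1.15 in hexenal and 4.14 ± 0.10 in mock (SD, n = 3), a difference of 2.82 ± 0.74 with a limma Benjamini-Hochberg adjusted p of 0.264. The defensin gene PDF1.2b (AT2G26020) was at 9.50 ± 0.90 against 5.83 ± 1.59, a difference of 3.67 ± 0.64 with a limma adjusted p of 0.0972, and AT5G02540 differed by -2.66 ± 0.35 with an adjusted p of 0.0529, both named after their values were seen. The probe set of PDF1.2b is of a kind that can also bind related transcripts, and PDF1.2 itself had 3.07 ± 1.01 (adjusted p = 0.405). limma called 0 of 22746 probe sets, and 0 of 16 lists passed camera or fry. In the fit without the replicate block 1577 probe sets had an unadjusted limma p under 0.05, against 1137 if none differed. Adjusted over the list alone 1 jasmonate response gene (PDF1.2) and 1 heat shock gene (AT2G29500) were higher. In the abscisic acid list 1 gene (COR47, -0.68 ± 0.20) was lower by that count. Without hexenal replicate 1 the count was 3, without hexenal replicate 2 it was 211, without mock replicate 2 it was 156, and without replicate 2 at every time it was 284, 197 higher and 87 lower.

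**Figure D2:**
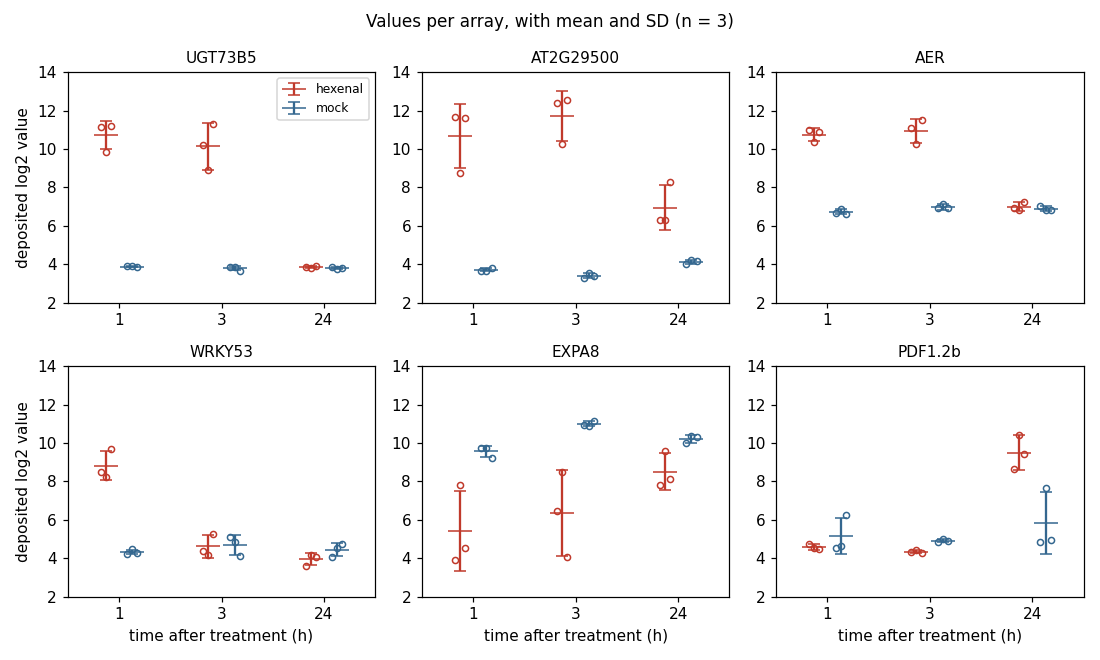
Deposited log2 value on each array (open circles), with group mean and SD (n = 3), of 6 genes in hexenal and mock leaves at 1, 3 and 24 h. UGT73B5 stands at a mean of 10.73 in hexenal at 1 h and 3.87 at 24 h, while mock stays between 3.80 and 3.89.

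The change of the response with time was tested as an interaction, the hexenal minus mock difference at one time minus that at another. From 1 h to 3 h the difference fell for AT5G52750 (-3.46 ± 0.50 on the log2 scale, SE, n = 3 arrays per group), from 4.09 ± 0.36 at 1 h to 0.64 ± 0.36 at 3 h, and for AT4G11000 (-2.72 ± 0.38), AT2G26190 (-2.67 ± 0.39), AT3G59080 (-2.63 ± 0.45) and AT2G24600 (-2.48 ± 0.34). It became more positive for AT5G24570 (1.70 ± 0.33, from -1.17 ± 0.24 to 0.53 ± 0.24), AT1G71140 (1.69 ± 0.33), AT5G17380 (1.65 ± 0.29), AT1G04810 (1.54 ± 0.30) and AT1G62050 (1.44 ± 0.13). Of these 10 genes, 5 kept their call whichever of the 12 arrays was left out. AT1G71140 and AT1G04810 lost theirs without 10 of the arrays, AT5G24570 and AT3G59080 without 9, and AT5G17380 without 8. WRKY53 dropped by 4.57 ± 0.52 between these times (limma adjusted p = 0.00318) and kept its call without any 1 array, while WRKY6 (-2.29 ± 0.83) did not pass (adjusted p = 0.340), except without hexenal replicate 3 of 3 h. Nor did STZ pass (limma adjusted p = 0.142), with the same exception. In all 85 probe sets passed limma with Benjamini-Hochberg adjustment, 41 with a more positive and 44 with a more negative difference at 3 h, and after median centring 42 and 30. The lists of WRKY factors (1 of 5 called), immunity (1 of 4) and touch, calcium and ZAT signalling (0 of 6) shifted downward by camera, with adjusted p of 0.00202, 0.000984 and 0.000857. With an estimated correlation the adjusted p was 0.0556, 0.255 and 0.255, and of the lists named here fry passed that of WRKY factors alone (adjusted p = 0.00106). Adjusted over the list alone 2, 1 and 3 genes fell. The photosynthesis list (0 of 10) shifted downward and the abscisic acid list (0 of 4) upward, with adjusted p of 0.0429 and 0.00998 and 0.652 and 0.229 with an estimated correlation, and 0 and 2 genes adjusted over the list alone. By camera the abscisic acid list was also lower in mock at 3 h than at 1 h, as given below, and its upward shift includes that change. The count of probe sets was 722 without hexenal replicate 2 of 3 h, 462 more positive and 260 more negative. It was 223 without hexenal replicate 2 of 1 h, 62 more positive and 161 more negative, 138 without hexenal replicate 3 of 3 h, and between 18 and 27 without hexenal replicate 3 of 1 h, hexenal replicate 1 of 3 h or any of the 6 mock arrays.

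From 3 h to 24 h the differences of AT4G01870 (-6.92 ± 0.46), AT5G51440 (-6.72 ± 1.28), ROF2 (-6.29 ± 1.25), UGT73B5 (-6.28 ± 0.62) and AT4G13180 (-5.78 ± 0.55) fell on the log2 scale. Those of PDF1.2b (4.23 ± 0.90), AT1G13650 (4.21 ± 0.70), AT4G28780 (3.26 ± 0.53), AT5G45670 (2.91 ± 0.64) and AT1G09750 (2.90 ± 0.75) became more positive. Of these 10 genes, 7 kept their call whichever of the 12 arrays was left out, while AT1G09750 lost its call without 10 of them, AT5G45670 without 3 and PDF1.2b without 1. limma with Benjamini-Hochberg adjustment called 1265 probe sets, 698 more positive and 567 more negative, and after median centring 493 and 585. A fit of these arrays alone called 396, 133 more positive and 263 more negative. The lists of heat shock (3 of 7 called), xenobiotic (3 of 5), carbonyl (3 of 8) and abscisic acid genes (2 of 4) shifted downward by camera, with adjusted p of 0.000165, 0.000388, 0.000388 and 0.00774. With an estimated correlation the adjusted p was 0.318, 0.274, 0.0880 and 0.204, and all 4 passed fry. Adjusted over the list alone 3, 3, 5 and 2 genes fell. The replicate block gave 1903, and the count was 4680 without hexenal replicate 2 of 3 h, 1747 and 1362 without mock and hexenal replicate 2 of 24 h, and between 444 and 731 without each other array. Without 8 of those 9 arrays the more negative were the more numerous, as in 187 more positive and 257 more negative without mock replicate 3 of 3 h.

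From 1 h to 24 h the differences of UGT73B5 (-6.79 ± 0.62), AT1G76600 (-6.75 ± 0.95), AT1G66090 (-6.67 ± 1.26), AT4G01870 (-6.61 ± 0.46) and AT5G25930 (-6.32 ± 1.16) fell, as did those of WRKY53 (-4.97 ± 0.52), WRKY6 (-4.60 ± 0.83) and STZ (-6.00 ± 0.99). They became more positive for PDF1.2b (4.22 ± 0.90), AT5G62210 (3.05 ± 0.50), PPR596 (AT1G80270, 2.30 ± 0.49), AT3G18600 (2.12 ± 0.44) and AT4G22560 (1.97 ± 0.45). Calls were lost for AT4G22560 without 10 of the 12 arrays, for PPR596 without 8, and for AT3G18600 and PDF1.2b without 6. The other 6 of the 10 genes named by size, and WRKY53, WRKY6 and STZ, kept theirs. limma with Benjamini-Hochberg adjustment called 567 probe sets, 160 more positive and 407 more negative. By camera 7 lists shifted downward, and those of WRKY factors (2 of 5 called) and carbonyl genes (3 of 8) held with an estimated correlation, each with an adjusted p of 0.0262. The others were touch, calcium and ZAT (2 of 6), immunity (2 of 4), xenobiotic (2 of 5), heat shock (1 of 7) and starvation genes (0 of 4). Their adjusted p with an estimated correlation was 0.0662, 0.0662, 0.121, 0.319 and 0.139, and heat shock (adjusted p = 0.208) and starvation (0.0680) did not pass fry. Adjusted over the list alone 3, 4, 5, 4, 3, 3 and 0 genes of these 7 lists fell. The count of probe sets was 1217 without hexenal replicate 2 of 1 h, 398 without mock replicate 1 of 24 h, and between 224 and 343 without each array not named here. It was 895 without hexenal replicate 2 of 24 h, 447 more positive and 448 more negative, and 824 without mock replicate 2 of 24 h, 361 and 463. With array weights it was 1744 and 1474.

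The calls at 1 h and 3 h rested on separate mock arrays but on the same variance per probe set. They were therefore not independent, and the counts for independent lists are a rough reference only. Of the 882 probe sets higher at 1 h, 464 were also called higher at 3 h, against 76.5 for independent lists, and of the 309 lower, 175 were also called lower, against 32.6. Another 4 were called in opposite directions. Across all probe sets, which are not independent replicates, the changes at 1 h and 3 h had a Pearson correlation of 0.770, and those at 1 h and 24 h one of -0.00898. The replicate block gave 974 shared calls in place of 639.

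Mock leaves were compared between times as the background of these changes. By 24 h AT4G30470 (3.06 ± 0.68), AT5G02540 (2.44 ± 0.35), AT2G17300 (2.35 ± 0.51), AT4G32460 (2.17 ± 0.23) and the tetraspanin gene TET3 (AT3G45600, 2.13 ± 0.32) were higher than at 1 h on the log2 scale (SE, n = 3 arrays per group). AT3G23550 (-3.56 ± 0.55), AT4G21870 (-3.35 ± 0.65), the cold-regulated gene COR15A (AT2G42540, -2.99 ± 0.32), AT2G41990 (-2.75 ± 0.63) and the allantoinase gene ALN (AT4G04955, -2.27 ± 0.51) were lower. Of these 10 genes 5 kept their call whichever of the 6 arrays was left out, while AT4G30470, AT2G17300, AT2G41990 and ALN lost theirs without 5 of them and AT4G21870 without 4. limma with Benjamini-Hochberg adjustment called 460 probe sets, 172 higher and 288 lower, and after median centring 457, 238 higher and 219 lower. Between 3 h and 1 h it called 14, 4 higher and 10 lower, among them AT1G04430 (-1.09 ± 0.14, adjusted p = 0.0119), whose call was lost without 5 of the 6 arrays. For 3 h the count was 7 without mock replicate 1 of 1 h, 1 without mock replicate 1 of 3 h and 0 without any other array. With all arrays 1708 probe sets had an unadjusted limma p under 0.05 for 3 h, against 1137 if none differed. For 24 h it was 914 without mock replicate 2 of 24 h, 450 higher and 464 lower, and between 167 and 246 without each other array, and fits of the mock arrays of the compared times alone gave 1728 for 3 h, 998 higher and 730 lower, and 273 for 24 h. Rises were also the more numerous for 3 h with array weights, 809 against 704, and with variance weights per group, 467 against 442. The abscisic acid list was lower in mock at 24 h than at 1 h, with 2 of 4 members called and 3 adjusted over the list alone (camera adjusted p = 0.000163, 0.0553 with an estimated correlation). It was also lower at 3 h, with none called and 2 adjusted over the list alone (camera adjusted p = 0.00168, 0.125 with an estimated correlation). Both passed fry.

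**Figure D3:**
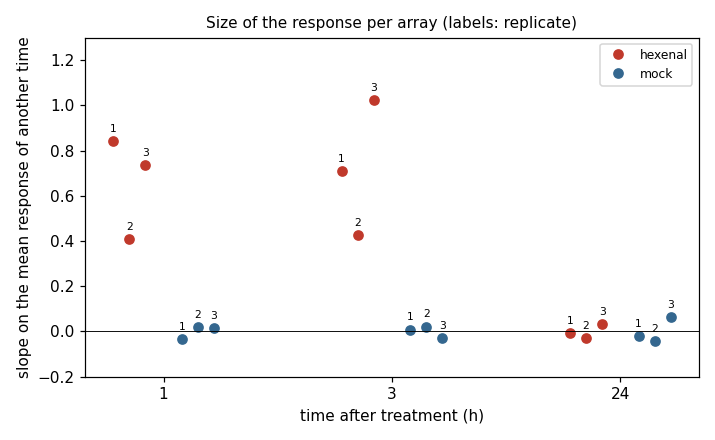
Size of the response on each array: slope of its change from the mock mean of its time (for a mock array, from the other mock arrays) on the mean response of another time, over the probe sets called at that other time, against time. The hexenal arrays at 1 h have slopes of 0.84, 0.41 and 0.74, those at 3 h 0.71, 0.43 and 1.02, and all arrays at 24 h lie between -0.04 and 0.06.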

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

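The tests on dose and on the hexenal arm of replicate 2 at 24 h were chosen after those results were seen, and the test on probe sets that fell was added after the first test of mixed RNA had left that question undecided. Differences between times were tested as interactions with limma and Benjamini-Hochberg adjustment, and they met the threshold for 85 probe sets between 3 h and 1 h, 1265 between 24 h and 3 h, and 567 between 24 h and 1 h. Between 3 h and 1 h they were 1.70 for AT5G24570, 1.69 for AT1G71140, 1.65 for AT5G17380, 1.54 for AT1G04810, 1.44 for AT1G62050, -3.46 for AT5G52750, -2.72 for AT4G11000, -2.67 for AT2G26190, -2.63 for AT3G59080 and -2.48 for AT2G24600 on the log2 scale. Between 24 h and 3 h they were 4.23 for PDF1.2b, 4.21 for AT1G13650, 3.26 for AT4G28780, 2.91 for AT5G45670, 2.90 for AT1G09750, -6.92 for AT4G01870, -6.72 for AT5G51440, -6.29 for ROF2, -6.28 for UGT73B5 and -5.78 for AT4G13180. Between 24 h and 1 h they were 4.22 for PDF1.2b, 3.05 for AT5G62210, 2.30 for PPR596, 2.12 for AT3G18600, 1.97 for AT4G22560, -6.79 for UGT73B5, -6.75 for AT1G76600, -6.67 for AT1G66090, -6.61 for AT4G01870 and -6.32 for AT5G25930.

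When the arrays of each arm were regrouped over the 2 times, 18 of 100 regroupings, the real one included, called as many probe sets as the 85 between 3 h and 1 h, with a highest other count of 357. For the 1265 between 24 h and 3 h it was 8 of 100 (highest other 3702), and for the 567 between 24 h and 1 h it was 7 of 100 (highest other 1762). Chance was not excluded for these 3 counts, but such regroupings can retain the change of an arm with time and so are no clean reference for an interaction. The hexenal arrays of each time stayed together in 5 of the 17, all 7 and all 6 other regroupings that reached these counts, a structure of the samples. For comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split was the 1 that called 1191 probe sets at 1 h, the 1 that called 4370 at 3 h and the 1 that called 14 in mock at 3 h, each with a highest other count of 0, and the 1 that called 460 in mock at 24 h, with a highest other of 1. At 24 h all 10 splits called at least the 0 of the real one, with a highest other of 702, and the 3 other splits that parted every same-numbered pair called 0, while those with 408 and 702 put a pair on one side, a structure of the samples.

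Hexenal replicate 2 at 1 h showed a smaller response than replicates 1 and 3, with 0.519 of their mean size along the 3 h response. Quantile normalization left that ratio at 0.522, which argues against remaining differences in distribution between the deposited arrays. Their medians already lay between 5.19 and 5.46, so this test cannot judge the unknown normalization behind the deposited values. Mock RNA mixed into this sample was not decided: the shortfall grew with the rise, with a slope of -0.27 ± 0.04 (SE, 366 probe sets), but by less than its error beyond the bound set in advance, and 171 probe sets that fell by 2 or more in the other replicates had a median of -0.87 in replicate 2, between the values set for and against; the rises would need a mock share of 71.6%, which would hold falls above -0.48, and the upper quartile of these falls was -0.62, which speaks against the mixture as the whole difference, but that share assumes plants that responded like those of the other replicates. That mixture and a lower dose or a weaker response of the plants, for which no measurement exists in the files used here, cannot be told apart, and replicate 2 was also the lowest at 3 h, with 0.43 against 0.71 and 1.02. In that other array the shortfall grew with the rise by -0.56 ± 0.06 (SE, 340 probe sets), past the bound set against mixed RNA for the 1 h sample. This does not decide on mixed RNA at either time. The shortfall and the rise share the mean of replicates 1 and 3, which can by itself make both slopes negative. At 3 h that mean includes the large response of replicate 3. The SE also treats probe sets of 1 array as independent.

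At 24 h both arrays of replicate 2 stood apart from the other arrays of their group, with 1194 probe sets deviating by 1 or more in the same direction in both arms. The deviations of the hexenal and the mock array had a correlation of 0.802 across probe sets, which argues against hexenal as their source. They also followed the mock change from 1 h to 3 h, with correlations of 0.298 in the hexenal arm and 0.340 in the mock arm, so a harvest at a clock time nearer to that of the 3 h samples is a candidate explanation; the labels give no clock time, and another difference shared by that experiment stays open.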

How the results depend on the processing

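The replicate block within each time, the block in fits of 1 time alone and the variance weights per group were chosen after the data were seen. No call of a named gene or list turned its direction under an alternative, while uncalled values of WRKY53 at 3 h (-0.71 to 0.23) and WRKY6 at 24 h (-0.16 to 0.05), and the directions of some uncalled lists, did. Deviations shared by all same-numbered pairs of arrays were seen at 24 h only, which does not show that the arrays of other times were unpaired. At 1 h the correlations of same-numbered deviations were -0.0703, 0.0728 and 0.289, and at 3 h 0.158, 0.128 and 0.0207. The block over all times moved the 3 counts given for it below by over 1.5 times, left the rest within that and changed no call of a list at 24 h. Median centring moved the median change by 0.10 at 3 h and by -0.13 for the 24 h to 3 h interaction. It gave 42 higher and 30 lower for the 3 h to 1 h interaction, against 41 and 44, and 238 and 219 for mock at 24 h, against 172 and 288. Of 124 values of named genes, the quantile normalization, the median centring and the replicate block each kept 120 on their side of the threshold, and 4 lost their call; the fits of the compared arrays alone kept 93 and lost 31. Without replicate 1, 2 or 3 at every time 101, 3 and 80 lost their call, and of 83 values in fits of 1 time alone with the block 37 did. Pseudocounts did not apply, and signal over background is not part of the table. The stricter thresholds and the brighter probe sets change counts by construction, as leaving out arrays does in part, and the cause of the other differences was not tested.

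With the replicate block the count was 1903 for the 24 h to 3 h interaction, 30 for mock at 3 h, 974 for shared calls. With the brighter probe sets alone the count was 3 for gene lists at 1 h, 2 for gene lists at 3 h, 1 for hexenal at 24 h, 47 for the 3 h to 1 h interaction. With quantile normalization the count was 2 for hexenal at 24 h, 29 for mock at 3 h. With median centring the count was 2 for hexenal at 24 h, 28 for mock at 3 h. With array weights estimated gene by gene the count was 5734 for hexenal at 1 h, 9924 for hexenal at 3 h, 251 for hexenal at 24 h, 2 for gene lists at 24 h, 2539 for the 3 h to 1 h interaction, 4968 for the 24 h to 3 h interaction, 3218 for the 24 h to 1 h interaction, 1513 for mock at 3 h, 2297 for mock at 24 h. The weights of hexenal replicates 1, 2 and 3 at 3 h were 5.38, 0.47 and 0.19, so such counts may reflect overstated weights. With an intensity trend and a robust prior the count was 8 for hexenal at 24 h. With an estimated correlation the count was 0 for gene lists at 3 h. With the compared arrays alone the count was 1833 for hexenal at 1 h, 1067 for hexenal at 3 h, 1 for gene lists at 24 h, 396 for the 24 h to 3 h interaction, 1728 for mock at 3 h, 273 for mock at 24 h. With a change of at least 2-fold the count was 2290 for hexenal at 3 h, 214 for mock at 24 h. With an adjusted p under 0.01 the count was 542 for hexenal at 1 h, 1473 for hexenal at 3 h, 12 for the 3 h to 1 h interaction, 229 for the 24 h to 3 h interaction, 166 for the 24 h to 1 h interaction, 0 for mock at 3 h, 134 for mock at 24 h. With a replicate block within each time the count was 1803 for hexenal at 1 h, 1 for gene lists at 24 h, 136 for the 3 h to 1 h interaction, 2074 for the 24 h to 3 h interaction. With variance weights per group the count was 3085 for hexenal at 1 h, 130 for the 3 h to 1 h interaction, 909 for mock at 3 h. With the compared arrays alone and the replicate block the count was 2004 for hexenal at 1 h, 116 for hexenal at 3 h, 1 for hexenal at 24 h. With 1 array or 1 replicate number left out, counts ranged from 67 to 2480 for hexenal at 1 h, from 6 to 7 for gene lists at 1 h, from 1 to 722 for the 3 h to 1 h interaction, from 1 to 2136 for the 24 h to 1 h interaction, from 0 to 17 for mock at 3 h, from 0 to 1517 for mock at 24 h, from 223 to 7215 for hexenal at 3 h, from 3 to 8 for gene lists at 3 h, from 13 to 4680 for the 24 h to 3 h interaction, from 0 to 284 for hexenal at 24 h, from 0 to 4 for gene lists at 24 h.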

Other observations

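The test of the proteasome genes below was set on a list written after 2 of its genes had been seen, and the families by name were formed after the data were seen. Of 51 measured genes with a UGT name, the glycosyltransferase family of UGT73B5, 7 were higher at 1 h and none lower, and 12 were higher and 1 lower at 3 h. The limma camera adjusted p over 31 families was 0.000152 at 1 h and 0.000151 at 3 h, and 0.106 and 0.249 with an estimated correlation. At 1 h genes with a PUB name (3 of 9 called) and a CML name (3 of 8), which share members with the lists of immunity and of touch and calcium signalling, were also higher by camera, with adjusted p of 7.04e-05 and 0.000313. Those with a TRM name (2 of 15 called) were lower, with 0.00614, and each of these 3 families had an adjusted p of 0.106 with an estimated correlation. At 24 h 8 genes with an OTP name, most of them pentatricopeptide repeat proteins of organelle RNA processing, had a median log2 change of 0.28 (camera adjusted p = 0.000267, 0.0467 with an estimated correlation), though none passed limma alone. Genes with ATGH, PRA and XTH names were lower at 24 h by camera, with none called and adjusted p of 0.0250, 0.0463 and 0.0496, and 0.399, 0.395 and 0.228 with an estimated correlation. These family values come from the fit without the replicate block, although same-numbered arrays shared deviations at 24 h.

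The 9 measured proteasome subunit genes, of 50 listed, had higher mean differences from mock at 3 h than at 1 h. RPN2B (AT1G04810) differed by -0.14 ± 0.21 at 1 h and 1.40 ± 0.21 at 3 h, and RPN11 (AT5G23540) by -0.13 ± 0.17 and 1.22 ± 0.17 (log2 change ± SE, n = 3 arrays per group). The 7 other measured subunit genes, which had not prompted the list, had medians of -0.15 at 1 h, 0.37 at 3 h and 0.14 at 24 h, and 2 of them, RPN7 (0.92 ± 0.18) and RPN3B (0.59 ± 0.19), passed limma at 3 h. For these 7 the interaction between 3 h and 1 h gave a camera p of 8.32e-06, and 0.0407 with an estimated correlation. None of them passed that interaction by limma alone, with RPN7 lowest (adjusted p = 0.0942). Leaving out hexenal replicate 3 of 3 h kept 0.946 of their median difference of 0.59, which argues against that array as the sole source. A coordinated rise of proteasome genes after the first hour of exposure is thus a hypothesis that these data are consistent with; an independent time course with more replicates would test it.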
